A study of Homo sapiens with 8 samples.

How the data were processed

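Gene expression was measured in IGROV-1 cells, an established human ovarian carcinoma line grown in the peritoneal cavity of mice. Tumor cells from 4 saline arrays and 4 CpG-ODN arrays were compared, 8 arrays in all, each sample on its own 1-colour Illumina bead array. CpG-ODN is a synthetic oligonucleotide with unmethylated CpG motifs that is recognised by Toll-like receptor 9. Per the labels, mice were injected with ascitic cells, treatment began 10 to 11 days later at 20 µg per mouse, and cells were collected 24 hours after the last treatment, with 4 mice in each group. The labels name a schedule of 3 consecutive days and one of 1 administration without saying which arrays had which, so the schedules were not separated.

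The deposited intensity values of the first table are average signals per probe that were not normalized, per the file headers, and the values show no background subtraction. BeadStudio is named in the submitters' processing notes, with no version. Beside each signal stands a deposited detection p-value, which falls as the signal rises. A second table of intensity values deposited by the authors had the same distribution on every array and the same order of probes within each array as the first, on the linear scale with no background subtracted. Its normalization method is not given in the sources used here. It served as an alternative.

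The signals were corrected for background and normalized with neqc in limma 3.58.1 under R 4.3.3, with the background distribution inferred from the detection p-values, an offset of 16 and quantile normalization. Of 48797 probes, 18184 had a detection p-value under 0.05 on at least 4 of the 8 arrays and were kept. Names came from the platform annotation through gene identifiers and the RefSeq gene table of GRCh38.p14, which was used for names and gene lengths alone. Of the kept probes, 14584 had 1 gene, 3 had several and 3597 are unnamed here. The named probes covered 11023 genes, and a gene was represented by its kept probe with the highest mean over all arrays.

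Probes were compared with lmFit and eBayes in limma with a term for treatment, two-sided, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. All adjusted p-values of single genes come from this limma fit. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists with at least 5 kept genes, beside camera with an estimated correlation and fry. In fry, the directional p asks whether the genes of a list move on balance one way and the mixed p whether they change in either direction, and neither compares the list with other genes. The gene lists, tests, alternatives and the rule for naming genes were fixed before the data were examined, apart from those named below as chosen afterwards. The rule took the 12 largest changes in each direction among probes with 1 gene symbol that passed the threshold and did not overlap between the groups, up to 4 members with the smallest p from each list, and TLR9.

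A probe that was not above background on any array of a group has only a bound there. Its fold is given as "at least", from the bright group's mean against the dim group's mean of, per array, the higher of the lowest detected signal and the probe's own signal. On simulated data with the spread of these arrays and 18184 probes, limma recovered 67 of 100 probes changed by 1 on the log2 scale and 7 of 100 changed by 0.5, with 0 false calls. The simulation changed 100 probes at each size, a far smaller share than the 26.6% called in the data. Its recovery and false calls therefore need not hold there. In the simulated list test over 11023 genes, camera found the shifted list and called 0 of 20 other lists. The simulated genes were drawn independently, so false calls from correlation between genes were not tested there.

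Alternatives covered the background correction, the normalization between arrays, the second table, the filter on dim probes, array weights, a mean-variance trend, a 1.5-fold threshold, the replicate number as a block, each array left out, the correlation in camera and the mean of all probes of a gene. No chip label was used here, so chip was not tested as a block. The precision is limited by the number of arrays. The labels give 4 mice per group, and no label ties an array to a mouse, so the p-values measure the spread between these arrays.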

Results

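Expression in IGROV-1 tumor cells was compared between mice given CpG-ODN and mice given saline into the peritoneal cavity, with 4 arrays in each group. The mean raw signal was 939 ± 93.9 (SD, n = 4) in saline and 899 ± 122 (SD, n = 4) with CpG-ODN, a difference within the spread of the arrays (exact permutation test, two-sided p = 0.514). The number of probes detected was 19452 ± 634 (SD, n = 4) in saline and 18491 ± 62.4 (SD, n = 4) with CpG-ODN (exact permutation test, two-sided p = 0.0286). The first principal component held 51.5% of the variance and separated the groups. Correlations between arrays ran from 0.982 to 0.988 within a group and from 0.959 to 0.972 between groups.

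The first question was how broadly locoregional CpG-ODN altered transcripts of the tumor cells. Levels of NPFFR2, a neuropeptide receptor gene, rose most among the genes named, by a log2 fold change of 2.96 ± 0.16 (SE, adjusted p = 1.54e-05). SCNN1A, a subunit of the epithelial sodium channel, rose by 2.13 ± 0.21, HMGA2, a chromatin architectural protein, by 2.13 ± 0.16, and the clock repressor gene NR1D2 by 2.15 ± 0.20. The antimicrobial peptide gene DEFB4A rose by 2.06 ± 0.47 and the noncoding RNA gene PVT1 by 2.00 ± 0.15. MAGOHB, PSMD9, EYA3, SLC51B, SMDT1 and TMEM171 also rose, by 1.99 to 2.23. Among genes that fell, ZNF702P changed by -2.62 ± 0.23, IGIP by -2.51 ± 0.23, and GRB10, an adaptor of receptor tyrosine kinases, by -2.21 ± 0.27. RBM4B, SLC35B3 and C9orf40 fell by log2 changes of -2.25 to -2.17. NAPEPLD, ZNF573, TM2D2 and FIRRM also fell, by fitted log2 changes of -2.33 to -2.14, but were above background on 1 of 4 CpG-ODN arrays, so the sizes rest mostly on background there. ZNF702P, IGIP and GRB10 were above background on 3 of 4 CpG-ODN arrays, NPFFR2 on 2 of 4 saline arrays, and MAGOHB and SLC51B on 3 of 4 saline arrays. The probe named for TAOK2 changed by -2.52 ± 0.22 while its other probe, above background on 2 of 4 saline arrays, stood at 0.45 (adjusted p = 0.194). The probe named for PPM1B changed by -2.40 ± 0.16, whereas another probe of that gene rose by 0.72 (adjusted p = 0.0441). Its remaining probe, brighter than the one that rose, stood at 0.06 (adjusted p = 0.82).

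In all, 4843 of 18184 probes changed, 26.6% of those tested, with 2322 higher and 2521 lower. At least a 2-fold change was seen for 409 of the higher and 645 of the lower probes. The groups did not overlap at 5253 probes (28.9%), where chance gives 2.86%. Counted by the brightest probe, 3218 of 11023 genes changed, 1417 up and 1801 down. Which direction held more probes depended on the processing, since median scaling called 2920 higher and 2195 lower and moved the median of all probes from 0.01 to 0.10.

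The next question concerned DNA repair. Many repair genes were lower with CpG-ODN: of 139 measured, 44 fell and 9 rose (50 and 13 adjusted over the list alone), with a median log2 fold change of -0.18. RMI1 and RAD54B, which act in homologous recombination, fell by log2 changes of -1.92 ± 0.17 and -1.65 ± 0.12, and the nuclease gene MUS81 by -1.09 ± 0.12. RAD51D was not above background on any CpG-ODN array and was at least 1.84-fold lower (adjusted p = 0.000227). The base excision repair glycosylase genes UNG, NEIL3 and MUTYH changed by -1.48 ± 0.14, -1.52 ± 0.25 and -1.12 ± 0.13, with NEIL3 above background on 3 of 4 CpG-ODN arrays. RAD23B, a partner of the damage sensor XPC, rose by 1.73 ± 0.16, whereas GTF2H1, a subunit of TFIIH, fell by a log2 change of -1.78 ± 0.17. The list was lower than other genes by camera (adjusted p = 0.00581, and adjusted p = 0.332 with an estimated correlation), and on balance lower by fry (adjusted p = 0.000207). Of the 35 ways to split the 8 arrays into equal groups, 3 gave a camera p at least as small for this list, the real one among them. The other 2 exchanged 1 array of each group, and among the 18 splits that mixed the groups equally the smallest p was 0.0884. With median scaling the median was -0.10, while that of all probes moved from 0.01 to 0.10 and the list stayed past the threshold (adjusted p = 0.00214).

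**Figure D1:**
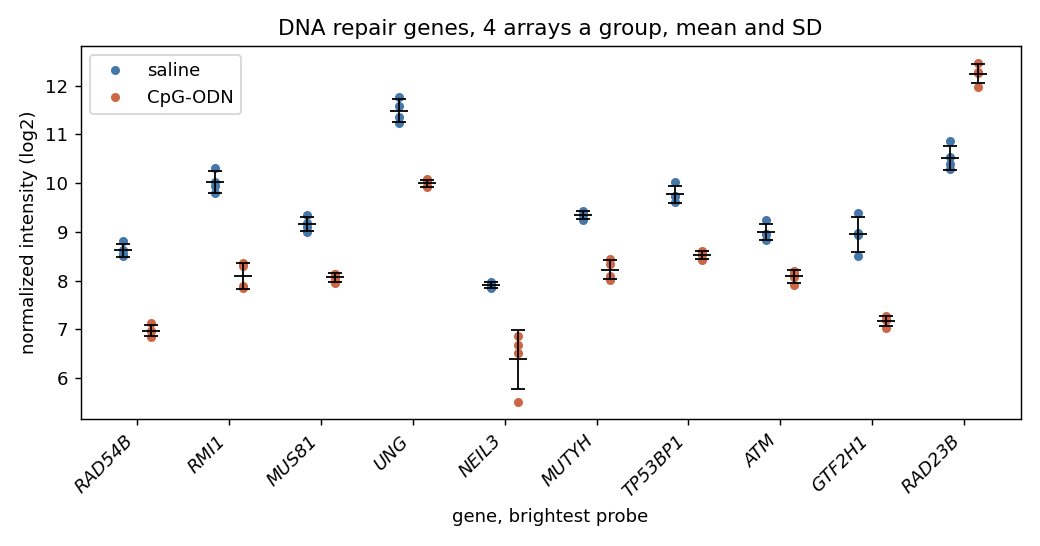
Normalized log2 intensity of 10 DNA repair genes on each of the 4 saline and 4 CpG-ODN arrays, with the gene on the horizontal axis, points for arrays, and bars for the mean and SD. RAD23B was higher with CpG-ODN and the other genes lower, for example RAD54B at 6.98 against 8.62 in saline. The 10 genes were picked from list members named for their small p. Of all 139 repair genes measured, 44 fell, 9 rose and 86 were not called.

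Within DNA repair, 15 of 30 homologous recombination and Fanconi anemia genes fell and 1 rose (16 and 2 adjusted over the list alone), with a median of -0.53 and an adjusted p of 0.000449 by camera (adjusted p = 0.182 with an estimated correlation). The median was -0.28 with no background correction and in the authors' normalized table. These settings called 5363 and 5364 probes as changed, so they are hardly separate checks. The correlation of the homologous recombination list was estimated at 0.0078, below the preset 0.01, and that of all repair genes at 0.0137. The gene that rose, FANCB, looked at after its value was seen, stood at 0.80 (adjusted p = 0.0018) while its dimmer probe was called the other way, not above background on any CpG-ODN array and at least 1.84-fold lower (adjusted p = 0.00101). Of 24 base excision repair genes, 11 fell and 1, MPG, rose (12 and 1 adjusted over the list alone), with adjusted p = 0.021 by camera and adjusted p = 0.332 with an estimated correlation. The other probe of MPG, above background on 3 of 4 saline and 2 of 4 CpG-ODN arrays, stood at -0.17 (adjusted p = 0.706). In mismatch repair 5 of 16 genes fell, among them EXO1 (-0.98 ± 0.15) and PMS1 (-1.57 ± 0.24, above background on 3 of 4 CpG-ODN arrays), and the list did not pass (adjusted p = 0.0667). It did pass with median scaling (adjusted p = 0.0318), with no filter on dim probes (adjusted p = 0.0132), with detection on at least 1 array (adjusted p = 0.0445) and without CpG-ODN replicate 4 (adjusted p = 0.0384). Checkpoint genes gave 8 lower and 2 higher of 19, with ATM at -0.91 ± 0.13, CHEK2 at -0.70 ± 0.14 and CHEK1 at -0.48 ± 0.11, and the list did not pass (adjusted p = 0.31). The other probes of EXO1 (-0.50, adjusted p = 0.111, above background on 3 of 4 CpG-ODN arrays) and CHEK2 (-0.32, adjusted p = 0.218) did not pass. Nucleotide excision repair had 3 lower and 1 higher of 25 (adjusted p = 0.909). End joining and translesion synthesis had 3 lower and 4 higher of 26 (adjusted p = 0.975), with TP53BP1 at -1.24 ± 0.12.

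Some proliferation genes fell, though most of those measured did not pass. Of 32 G1/S and replication genes 12 fell and 0 rose (13 and 0 adjusted over the list alone), including the replication factor gene MCM10 (-1.56 ± 0.16), MCM6 (-0.75 ± 0.12) and CCNE1 (-0.90 ± 0.14). Of 37 mitotic genes 15 fell and 0 rose (17 and 0 adjusted over the list alone), including HMMR (-1.76 ± 0.11) and the kinetochore motor gene CENPE (-0.87 ± 0.16). The adjusted p by camera was 0.000228 for the first list (adjusted p = 0.332 with an estimated correlation) and 0.000285 for the second (adjusted p = 0.429 with an estimated correlation). These lists, the repair genes as a whole and the homologous recombination and base excision lists made up the 5 of 32 lists past the threshold, all lower, and 0 passed with an estimated correlation. As many as 7 lists passed in another split of the arrays, and 7 of the 35 splits, the real one among them, gave at least 5. Of the 18 that mixed the groups equally, 2 gave at least 5.

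The type I interferon genes went both ways and did not pass as a list. Of 45 measured, 12 fell and 5 rose (14 and 5 adjusted over the list alone), with a median log2 fold change of -0.11 and adjusted p = 0.357 by camera. Single arrays moved this median, to -0.03 without CpG-ODN replicate 3 and to -0.21 without CpG-ODN replicate 1. By fry, which does not set the list against other genes, they were on balance lower (adjusted p = 0.0238). IFIT2 and IFIT3, antiviral effector genes, rose by 1.36 ± 0.14 and 1.40 ± 0.15, while IRF9, a subunit of the interferon-activated transcription factor, fell by a log2 change of -0.83 ± 0.12 and SP100, above background on 3 of 4 CpG-ODN arrays, of -0.80 ± 0.13. Interferon gamma and antigen presentation genes had 3 higher and 4 lower of 26 (adjusted p = 0.877), with HLA-E at 0.62 ± 0.12. TAP2 stood at 1.20 ± 0.17 by the probe named and at 0.07 by its other probe (adjusted p = 0.805). TLR9, the receptor of CpG-ODN, was not above background on any of the 8 arrays. The Toll-like receptor and nucleic acid sensing list had 4 higher and 6 lower of 19 (adjusted p = 0.614), with TICAM2 at -1.77 ± 0.19, CGAS at -1.03 ± 0.16 and TBK1 at 0.59 ± 0.12. NF-kB and cytokine genes went both ways, with 5 higher and 6 lower of 34 (adjusted p = 0.975). The chemokine gene CXCL8 changed by -2.05 ± 0.47 and the acute phase gene SAA1 by 1.05 ± 0.21. For CXCL8 the groups overlapped, with saline replicate 4 at 10.91 and CpG-ODN replicate 1 at 11.06.

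Stress and metabolic lists did not pass camera in the main setting. The hypoxia and glycolysis list had 8 lower and 2 higher of 34 (adjusted p = 0.0667), with ENO2 at -1.13 ± 0.14, and it passed in 9 alternatives. The heat shock list had 8 lower and 3 higher of 26 (adjusted p = 0.844), with the chaperone genes HSPH1 and HSPA1B at -1.82 ± 0.13 and -1.19 ± 0.19. Among p53 targets 6 rose and 2 fell of 19 (adjusted p = 0.574), with GADD45A at 0.91 ± 0.17. BAX, looked at after its value was seen, was among those that fell, at -0.51 (adjusted p = 0.0419). Its dimmer probe rose by 0.58 (adjusted p = 0.0145). The adjusted p was 0.975 for apoptosis regulators, endoplasmic reticulum stress and cholesterol synthesis, and 0.584 for metallothionein and ribosomal protein genes. It was 0.37 for the respiratory chain and 0.21 for the proteasome, and ribosomal protein genes had 0 calls among 43. With median scaling these 3 lists passed as higher, with medians of 0.27 for ribosomal proteins, 0.29 for the respiratory chain and 0.30 for the proteasome. Epithelial genes had an adjusted p of 0.877, mesenchymal genes 0.975 and ovarian carcinoma markers 0.673, and CCN2 of the mesenchymal list rose by 1.53 ± 0.16. Among 12 housekeeping genes TBP fell by a log2 change of -0.99 ± 0.12, IPO8 fell by -0.64 ± 0.12 and PPIA rose by 0.52 ± 0.12 (list adjusted p = 0.584). Beside the type I interferon list, other lists that camera did not call passed by fry. With a negative median these were mismatch repair (adjusted p = 0.000391), checkpoint (0.00112), hypoxia and glycolysis (0.0162), nucleic acid sensing (0.0227) and housekeeping (0.0227). With a positive median they were p53 targets (0.0153), endothelial (0.0227), proteasome (0.0377), macrophage (0.0418) and ovarian carcinoma markers (0.0436). The housekeeping list was a control, so a pass by fry alone does not set a list apart from other genes. The median, mean and test of a list differed in sign for interferon gamma, apoptosis, cholesterol, epithelial, mesenchymal and mesothelial genes.

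Markers of other cells were few among the detected probes, on an array made for human transcripts. Of 6 macrophage markers measured, CD14 (0.76 ± 0.19) and CD68 (0.65 ± 0.16) rose and AIF1 fell by a log2 change of -1.09 ± 0.31 (list adjusted p = 0.649). The other probes of CD68 did not pass, at 0.38 (adjusted p = 0.408) and 0.85 (adjusted p = 0.0567). CD14 was above background on 1 of 4 saline and 3 of 4 CpG-ODN arrays. The call of AIF1 was lost without saline replicate 3 (adjusted p = 0.0569) and without CpG-ODN replicate 1 (adjusted p = 0.0654). Of 5 endothelial markers VWF rose by 1.02 ± 0.20 and CDH5 by 0.63 ± 0.19 (list adjusted p = 0.296). The call of CDH5 was lost on leaving out any 1 array other than CpG-ODN replicate 4, with adjusted p from 0.0527 to 0.0844, and with the replicate number as a block (adjusted p = 0.0537). Fibroblast markers had 1 higher and 1 lower of 9, MFAP5 at 1.13 ± 0.18 and ACTA2 at -1.15 ± 0.14 (list adjusted p = 0.909). Mesothelial markers had 1 higher and 1 lower of 5, and skeletal muscle markers 0 of 5, with list adjusted p-values of 0.975 each. Both mesothelial calls, UPK3B and LRRN4, were lost with the replicate number as a block (adjusted p = 0.113 and 0.0698) and each was lost on leaving out 6 of the 8 arrays singly, not the same 6 for both. Neutrophil, lymphocyte, erythroid and adipocyte or liver lists had under 5 genes kept and 0 calls.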

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

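The tests of host markers and of cell-cycle-linked repair genes, and the grouping of splits by the arrays they exchanged, were chosen only after the results were seen. The number of changed probes was set against the other splits of the 8 arrays into 4 and 4. The real split gave 4843 and the highest of the other splits 0. Only 1 of the 35 splits, the real one, gave as many, the smallest share that 35 splits can give. Exchanging arrays also puts the group difference into the spread within groups, which lowers the calls of the other splits. Chance is therefore unlikely for this count but not excluded. With the mean raw signal of each array as a covariate, 91.0% of the called probes stayed called in the same direction. Mean raw signal differed little between the groups (939 ± 93.9 in saline and 899 ± 122 with CpG-ODN, SD, n = 4), and the values were already quantile normalized. Such a covariate could remove few calls, so the result does not decide on brightness as a cause. Probes detected, which ran from 18784 to 20114 in saline and from 18425 to 18570 with CpG-ODN, separated the groups and was not tested as a covariate. Host mouse RNA behind the higher probes cannot be told apart from a change in the tumor cells, because 28.6% of the 14 kept markers of white blood cells and vessels rose, 4 rising and 1 falling, and the mouse transcripts' binding to these probes is unknown. An effect of treatment stays open, and chip was not tested, since no label used here gives it.

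For the lower DNA repair genes, 3 of the 35 splits gave a camera p as small as the real 0.000726, with 0.00047 the smallest of the others, so the count over all splits does not exclude chance. The other 2 exchanged 1 array of each group and so held part of the treatment difference, while the 18 splits that mixed the groups equally gave no p under 0.0884, a set too small for a share under 0.05. Low brightness of the probes does not account for the shift, since the median lay at percentile 0 of 10000 random lists matched on mean expression, and gene length does not either, at percentile 0.01, though such lists take genes as independent. Fewer dividing cells may contribute: the 40 cycle-linked repair genes had a median of -0.45 and the other 99 of -0.17 (permutation test over genes, p = 0.02). That permutation also takes genes as independent, so its p does not measure the spread between arrays. The other 99 lay at percentile 0.08 of random lists matched on mean expression, which take genes as independent. Without the linked genes camera no longer called the list (adjusted p = 0.0923), so whether fewer dividing cells are the whole cause stays open.

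The number of lists past the threshold was 5, with 7 the highest of the other splits, and 7 of the 35 splits gave as many, 2 of them among the 18 that mixed the groups equally, so chance cannot be excluded for it. For the type I interferon genes 13 of the 35 splits gave a camera p as small as the real 0.123, with 0.00208 the smallest of the others.

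Single arrays stood far from the other 3 of their group in 14 of 336 groups examined, and chance gives about 1 in 20. The gap took a share of 0.838 of the range of mean raw signal in saline, where replicate 1 was the brightest. In saline the share was 0.865 for PMS1, 0.876 for CXCL8 and 0.831 for MCM6, each set by replicate 4. It was 0.902 for MCM10 and 0.922 for CDH5, set by saline replicate 3, and 0.831 for NDUFB5 and 0.858 for S100A9, set by saline replicate 1. With CpG-ODN the share was 0.863 for DCLRE1A, set by replicate 3, and 0.851 for CHEK2 and 0.86 for TBP, set by replicate 2. It was 0.947 for AIF1 and 0.851 for BHLHE40, set by CpG-ODN replicate 1, and 0.901 for TIE1, set by CpG-ODN replicate 4.

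Of 6 probes held by the authors' normalized table alone, that of CTNNBIP1 did not overlap between the groups, at 517 ± 32.3 (SD, n = 4) in saline and 991 ± 147 (SD, n = 4) with CpG-ODN, 1.9-fold higher (exact permutation test, two-sided p = 0.0286, adjusted p = 0.171 over the 6 probes).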

How the results depend on the processing

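Adding the removal of cycle-linked repair genes was chosen after seeing the data. The count of changed probes stayed within 1.5 times of 4843 under all alternatives run, and no called probe was called in the opposite direction. Leaving out each array gave 3866 to 4266. With a 1.5-fold threshold 1484 probes were higher. The share of changed probes that were higher was 47.9%, and it passed to the other side with median scaling (57.1%) and with detection at 0.01 on all 8 arrays (51.2%). Median scaling also moved the median of all probes from 0.01 to 0.10, and for the stricter filter the cause was not tested. The lists past the threshold numbered 9 with median scaling, where the ribosomal, respiratory chain and proteasome lists joined as higher and mismatch repair as lower, and 0 with an estimated correlation. The DNA repair median of -0.18 was no longer past the threshold with an estimated correlation (-0.18, adjusted p = 0.332) or without the cycle-linked genes (-0.17, adjusted p = 0.0923), and stayed past it otherwise, with a median of -0.10 under median scaling, beside that shift of all probes. The homologous recombination median of -0.53 was -0.28 with no background correction and in the authors' table, and -0.38 with normexp from the signals alone. The type I interferon median of -0.11 was -0.06 with detection at 0.01 on all 8 arrays and ran from -0.21 to -0.03 as each array was left out, and the list was not called in any alternative. The hypoxia list passed in 9 alternatives and mismatch repair in 4. Those 9 include no background correction and the authors' table, which gave nearly the same camera result (adjusted p = 0.0299 and 0.0300). Of 123 named genes called, 110 stayed called under every alternative run for single genes that kept the probe, and none reversed. The 1.5-fold threshold was not applied to single genes. Dim probes limit what could be called, and chip as a block was not run.

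Equal replicate numbers did not pair the arrays: their deviations correlated at 0.02, -0.05, -0.27 and 0.09, and 0 numbers had arrays that correlated best with each other. With the replicate block 3954 probes changed, and no list call changed.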

Other observations

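The tests of lists, of time of day and of probe pairs in this part were chosen after the fold changes were seen. Single-gene values come from the planned limma fit. Several genes of the circadian clock were higher with CpG-ODN. Of 14 measured, 7 rose and 1 fell, with a median log2 fold change of 0.52 (camera p = 0.00109, and p = 0.0254 with an estimated correlation, neither adjusted). NR1D2 rose by 2.15, TEF by 1.14, DBP by 1.03, PER2 by 0.79, CRY2 by 0.75, CRY1 by 0.67 and NFIL3 by 0.62, and CLOCK fell by a log2 change of -0.57. NR1D1 was not above background on any array. A different time of day at collection is a candidate explanation that the data leave open, because 1 of BMAL1, NPAS2 and CLOCK passed the threshold and BMAL1 stood at 0.15 (adjusted p = 0.381). The labels used here give no time of day.

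Small nucleolar RNAs had 13 higher and 4 lower of 42 measured (camera p = 0.00539, and p = 0.29 with an estimated correlation, neither adjusted). Where 2 probes of a gene were both called, they pointed in opposite directions at 29 of 451 genes. That was the case for 21 of 154 genes whose probes had different accessions and 8 of 297 whose probes shared one (Fisher's exact test, p = 1.9e-05). HBA2, a hemoglobin gene, was bright in both groups, at 12.67 in saline and 12.45 with CpG-ODN (adjusted p = 0.777).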
